A study of Nelumbo nucifera with 6 samples.

How the data were processed

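The data are 6 RNA-seq libraries of lotus rhizomes, 3 from consecutive planting and 3 from first-year planting, grouped by the labels. Per the labels' protocols, messenger RNA was enriched from 1 ug of total RNA with oligo(dT) beads, fragmented to about 200 bp, primed randomly and sequenced on a BGISEQ-500 instrument. HISAT and Bowtie2 are named in the submitters' processing notes, without versions or roles. The counting tool, genome build and annotation are not given in the sources used here. Each deposited table, per the file headers, gives 1 library's expected counts per gene, which are estimates of the fragments of each gene and need not be whole. The FPKM values were deposited by the authors beside the expected counts and, per the file headers, scale them by gene length and library total. The tables list only genes with an expected count above 0, so a gene missing from a table was taken as 0 in that library. Between 85.1% and 85.5% of expected counts were whole to within the 2 decimals given. Fractional counts can arise where reads fit another gene or copy as well. That origin was not checked here, and such values were taken as uncertain. Strand use in the counting is not given either, so overlapping and antisense genes could not be told apart.

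Descriptions in the tables named the genes, by the first informative entry where a gene had several. Of 25130 genes, 24737 had a description, 22963 carried reference identifiers and 2167 a separate prefix. No genome was used here, and no coordinates or GC content are given.

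Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F test, trimmed-mean (TMM) factors, default filter on low counts by group) in R 4.3.3, with group as the term. Benjamini-Hochberg adjusted p below 0.05 was the threshold. The TMM factors were 1.11 to 1.12 in consecutive planting and 0.888 to 0.903 in first-year planting. FPKM values carry no such factor, so ratios of mean FPKM exceed the fitted folds of genes that rose. Log2 fold changes are fitted values, with the SE of the difference of mean log2 CPM (prior count 2). A gene at 0 in a whole group was given a lower bound against 3 counts over that group, and a gene with 1 to 3 counts the ratio with its 95% exact counting interval; both cover counting error only. At these depths 3 counts in a single library correspond to between 0.118 and 0.128 CPM. The floor of 3 counts over all libraries of a group lies lower than that.

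The 34 gene lists were written as text patterns on descriptions. Each was compared with all other tested genes by camera of limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01 and adjustment over the 34 lists. After the tables were read, some patterns were found to take in mismatched genes, such as calcyclin-binding proteins among cell cycle genes, and the lists were kept as written. Named genes followed a rule: the 8 largest rises and 8 largest falls with adjusted p below 0.05, no overlap between groups, a mean of at least 5 FPKM in the higher group and an informative description; up to 3 members with the smallest p in each of the 6 lists with the smallest camera p; and the member with the smallest p of each other list. The groups, tests, lists, naming rule and most of the other settings below were set before the data were examined. With the 225 tested genes at 0 in a group set to their bound, no list median changed. This could hardly come out otherwise, since a gene at its bound stays on its own side of the median.

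Replicates were compared first. Over genes with whole counts, chi-square per degree of freedom between libraries of a group lay between 1.52 and 3.18, above sampling noise in every pair, so all 6 libraries were kept. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.99 to 0.991 within groups and 0.716 to 0.721 between them. The first principal component held 95.8% of the variance and separated the groups. No batch is given in the labels.

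The other settings set at that time were other scalings (RLE size factors, total counts), no filter or at least 1 FPKM in 3 libraries, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, each library left out, and for lists an estimated correlation and fry. A glmTreat test against 2-fold, lists ranked by fold change (cameraPR) and lists without mismatched members were added after seeing the data. On simulated counts for 20629 genes at the real library sizes, the edgeR step recovered 54% of genes at the smallest simulated change. It recovered 92% at 1.5-fold, 95.9% at 2-fold and 100% at 4-fold. Of its calls 9.57% (18 genes) were false, above the nominal 5%. Only 49 or 50 genes were changed at each size. In the real comparison most tested genes were called, so this share does not carry over to it. Camera recovered 2 of 2 lists shifted by 2 on the log2 scale and called 0 of 32 others. With an estimated correlation it recovered 1 of 2, and fry called 30 of the 32 others. Changes were drawn independently for each gene, so false calls from correlation within a list could not appear. Fry does not compare a list with other genes, and genes of the other lists were changed too, so its 30 calls are not errors. Python 3.11.15 joined the tables.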

Results

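Messenger RNA was profiled in rhizomes, the edible underground stems, of the sacred lotus Nelumbo nucifera, cultivar Taikonglian 36. The plants had grown in 10 pools. In 5 pools lotus had never been planted before (first-year planting), and in the other 5 pools lotus had been planted for 4 years in succession (consecutive planting). Each group had 3 libraries. The tables held expected counts and FPKM for 25130 genes, of which 20583 were listed in all 6 libraries. Total expected counts were 25033731, 24920990 and 25331460 in the consecutive-planting libraries and 23802075, 23603851 and 23520287 in the first-year libraries. The consecutive-planting libraries listed between 23156 and 23185 genes each, and the first-year libraries between 22537 and 22555. With at least 10 counts in each library of its own group, 146 genes were listed in all consecutive-planting libraries and in no first-year library, and 87 genes the other way round. The gene with the most expected counts in the consecutive-planting libraries, not scaled by gene length, was elongation factor 1-alpha (NNU_10047), with 0.835% to 0.89% of counts. In the first-year libraries it was S-adenosylmethionine synthase 2 (NNU_25903) in replicate 1, with 0.697%, and heat shock cognate 70 kDa protein 2-like (NNU_12294) in replicates 2 and 3, with 0.716% and 0.705%.

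The comparison of the planting groups asked which rhizome transcripts differ once lotus has been replanted in the same pools, the setting in which replant disease arises. By camera with a preset correlation between genes, the lists of ribosomal, cell cycle, histone, proteasome, flavonoid synthesis and cell wall loosening genes lay higher in consecutive planting, but none of these 6 passed with the correlation estimated from the libraries. The lists of WRKY transcription factors, heat shock proteins, mineral nutrient transporters, starch synthesis and starch breakdown lay lower. None of these 5 passed with an estimated correlation either. For cell cycle, mineral nutrient transporter and starch breakdown genes the estimate lay below the preset value, so a larger correlation is not why they failed. Mixed splits of the libraries, each holding libraries of both groups on either side, called between 6 and 10 lists by the same preset test. The real grouping called 11. Each mixed split holds unequal numbers of the groups on a side and so keeps part of the group difference. Its lists are therefore not a count of false calls. Of 20629 genes tested, 9015 were higher and 8577 lower in consecutive planting, which is 85.3% of those tested. At least 2-fold, 5013 genes were higher and 4230 lower. Scaled by total counts alone, 11339 genes were higher and 6515 lower, since that scaling moved the median log2 fold change of all genes from 0.03 to 0.35, and directions below are relative to the trimmed-mean scaling. The spread within groups was small, with a common biological coefficient of variation of 3.63%. The labels speak of 6 rhizomes without tying them to pools, so p-values measure only the spread between these samples, which may be technical.

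Among genes with the largest rises, several were listed in no first-year library. The WAT1-related protein NNU_24842, of a family of membrane transporters, reached 24.4 ± 2.41 FPKM (SD, n = 3) in consecutive planting and was at least 462-fold higher, taking 3 counts over the first-year group as the floor. On the same floor the ABC transporter G family member 15-like gene NNU_01633 was at least 384-fold higher, the GDSL esterase/lipase NNU_12066 at least 334-fold and the (RS)-norcoclaurine 6-O-methyltransferase-like gene NNU_25948, named for a step of benzylisoquinoline alkaloid synthesis, at least 329-fold. The polygalacturonase NNU_25881, a pectin-degrading enzyme, was at least 296-fold higher. The tocopherol O-methyltransferase NNU_09848 and the acyl-activating enzyme NNU_17683 were at least 314-fold and 270-fold higher. Their counts were fractional, which may come from reads shared with other genes, so these values are uncertain. The lipid-transfer protein DIR1 gene NNU_21235 had 163 ± 11.4 FPKM (SD, n = 3) in consecutive planting and 1 count in the first-year group, a ratio of 4028 with a 95% counting interval from 723 to 159140.

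Among genes with the largest falls, several had no count in consecutive planting. Peroxidase 72-like (NNU_01589) had 18.3 ± 0.808 FPKM (SD, n = 3) in first-year planting and no count in consecutive planting, at least 539-fold lower. Cytochrome P450 86A1 (NNU_03774) and cytochrome P450 86B1 (NNU_22543), fatty acid hydroxylases of suberin synthesis, were at least 419-fold and 311-fold lower. A list of suberin and Casparian strip genes, written after the largest changes had been seen and holding these 3 genes, rose in 18 of 42 members and fell in 22 and did not pass camera (adjusted p = 0.312; adjusted p = 0.303 with an estimated correlation). Ranked by fold change, a test chosen after seeing the data, it lay lower in limma (adjusted p = 0.0262), to which the genes that prompted the list contribute. Adjustment for this list was over the 4 lists written at that time, not over the 34. Among its members NNU_25346 rose by 7.34 on the log2 scale and BGI_novel_G002176 was at least 231-fold higher (both chosen after their values were seen). The ethylene-responsive factor ERF024-like (NNU_19472) was at least 419-fold lower, the glucan endo-1,3-beta-glucosidase NNU_03185 at least 377-fold, and the collagen alpha-2(I) chain-like gene NNU_03264, which also had fractional counts, at least 511-fold. The elicitor-responsive protein 1-like gene NNU_18777 fell from 475 ± 6.9 to 0.2 ± 0 FPKM (SD, n = 3 each), a ratio of 2769 in scaled counts. The lysosomal Pro-X carboxypeptidase-like gene NNU_17018 had 1 count in consecutive planting, a ratio of 4341 with a 95% counting interval from 779 to 171510. All 16 of these genes had an edgeR quasi-likelihood adjusted p of at most 1.59e-10.

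**Figure D1:**
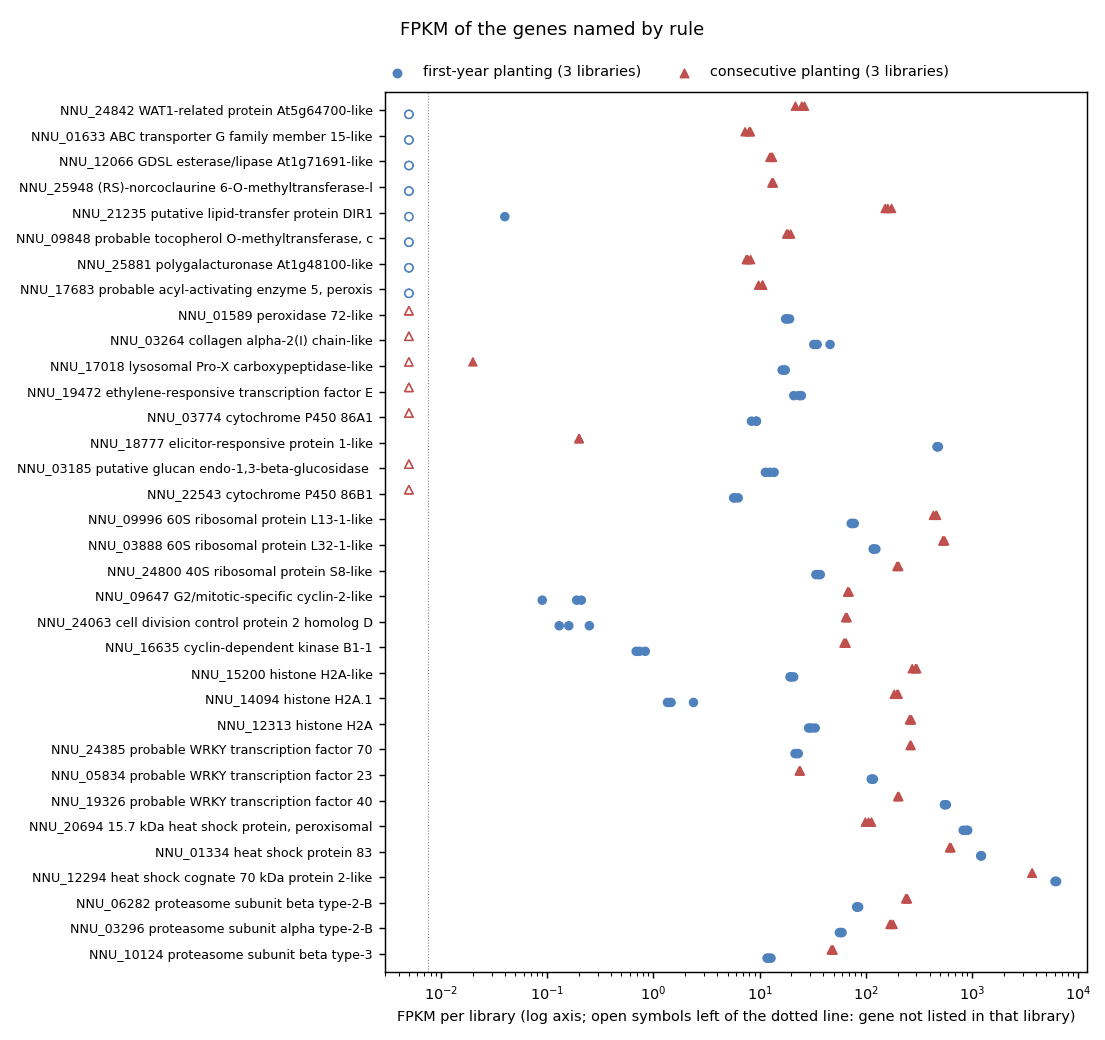
FPKM of each library on a log axis for the genes with the largest rises and falls and for leading members of 6 gene lists, with triangles for the 3 consecutive-planting and circles for the 3 first-year libraries. Open symbols left of the dotted line mark libraries in which the gene was not listed; the elicitor-responsive protein 1-like gene NNU_18777 lies at 475 FPKM in first-year and 0.2 FPKM in consecutive planting.

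Cytosolic ribosomal proteins, the components of the translation machinery, rose in 187 of 206 tested members, fell in 9 and did not pass in 10. The median log2 fold change was 0.71, and the list lay higher than other genes by camera (adjusted p = 8.18e-14; adjusted p = 0.284 with an estimated correlation). The 60S ribosomal protein L32-1-like gene NNU_03888 rose from 120 ± 3.76 to 541 ± 11 FPKM (SD, n = 3 each), a log2 fold change of 1.85 ± 0.02 (SE). The L13-1-like gene NNU_09996 and the 40S S8-like gene NNU_24800 rose by 2.30 and 2.23 on the log2 scale, with fractional counts in both.

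Of 118 cell cycle genes 83 rose, 24 fell and 11 did not pass, with a median log2 fold change of 1.59 (camera adjusted p = 9.7e-05; adjusted p = 0.121 with an estimated correlation). The mitotic cyclin NNU_09647, which acts at the entry to mitosis, rose from 0.163 ± 0.0643 to 68.5 ± 1.16 FPKM (SD, n = 3 each). Cyclin-dependent kinase B1-1 (NNU_16635) rose from 0.757 ± 0.0764 to 64.1 ± 1.53 FPKM (SD, n = 3 each), and the cell division control protein 2 homolog D (NNU_24063), with fractional counts, rose by 8.40 on the log2 scale. Histones rose in 27 of 35 members, fell in 4 and did not pass in 4, with a median of 2.12 (camera adjusted p = 0.000658; adjusted p = 0.309 with an estimated correlation). The histone H2A genes NNU_15200, NNU_14094 and NNU_12313 rose by 3.54, 6.48 and 2.77 on the log2 scale. Cuticle and wax genes, listed after the largest changes had been seen, rose as well (24 of 31 members, camera adjusted p = 0.000875, adjusted p = 0.0542 with an estimated correlation). Both values were adjusted over the 4 lists written at that time, not over the 34. Unadjusted, camera with an estimated correlation gave p = 0.0135 for this list and p = 0.00356 for cell cycle genes. The labels give no part or stage of the rhizome.

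Proteasome subunits, which degrade ubiquitin-tagged proteins, rose in 50 of 71 members, fell in 8 and did not pass in 13 (camera adjusted p = 0.00234; adjusted p = 0.428 with an estimated correlation). Their median log2 fold change was 0.39, and with genes ranked by fold change, a test chosen after seeing the data, the list did not pass (adjusted p = 0.638). The subunits beta type-2-B (NNU_06282), alpha type-2-B (NNU_03296) and beta type-3 (NNU_10124) rose by 1.22, 1.26 and 1.64 on the log2 scale. Flavonoid synthesis genes rose in 44 of 66 members, fell in 17 and did not pass in 5 (camera adjusted p = 0.00809; adjusted p = 0.478 with an estimated correlation). Flavonoid 3',5'-hydroxylase 2-like (NNU_24191), with fractional counts, rose by 4.08 on the log2 scale. Cell wall loosening genes rose in 67 of 111 members, fell in 37 and did not pass in 7 (camera adjusted p = 0.0211; adjusted p = 0.428 with an estimated correlation). Its member with the smallest p went the other way, since the xyloglucan endotransglucosylase/hydrolase NNU_15030, with fractional counts, fell from 2467 ± 43.2 to 74.3 ± 1.69 FPKM (SD, n = 3 each). Without a filter on low counts, and on log2(FPKM + 1), the cell wall loosening list did not pass camera (adjusted p = 0.113 and 0.103). Its median log2 fold change was 1.92, and it passed when ranked by fold change (adjusted p = 1.29e-06), the test chosen after seeing the data.

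WRKY transcription factors, many of which act in defence, fell in 39 of 54 members, rose in 12 and did not pass in 3, with a median log2 fold change of -1.33 (camera adjusted p = 0.00137; adjusted p = 0.428 with an estimated correlation). WRKY 40 (NNU_19326) fell from 561 ± 12 to 203 ± 2.22 FPKM and WRKY 23 (NNU_05834) from 116 ± 2.68 to 24 ± 0.278 FPKM (SD, n = 3 each). WRKY 70 (NNU_24385) rose from 22.4 ± 0.798 to 265 ± 2.42 FPKM (SD, n = 3 each). Heat shock proteins, which are chaperones, fell in 46 of 66 members, rose in 14 and did not pass in 6, with a median of -0.44 (camera adjusted p = 0.00224; adjusted p = 0.309 with an estimated correlation). Scaled by total counts alone, 34 fell and 24 rose. The peroxisomal 15.7 kDa heat shock protein NNU_20694 fell by 3.36 on the log2 scale, heat shock protein 83 (NNU_01334), with fractional counts in 1 library, fell by 1.29, and heat shock cognate 70 kDa protein 2-like (NNU_12294), with fractional counts, fell by 1.11.

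Mineral nutrient transporters fell in 108 of 175 members, rose in 51 and did not pass in 16, with a median log2 fold change of -0.72 (camera adjusted p = 0.00809; adjusted p = 0.284 with an estimated correlation). The NRT1/PTR family 6.2 gene NNU_21647 fell by 6.65 on the log2 scale. Starch synthesis genes fell in 16 of 24 members, rose in 5 and did not pass in 3 (camera adjusted p = 0.0352; adjusted p = 0.428 with an estimated correlation). Granule-bound starch synthase 1 (NNU_17798), which makes amylose, fell from 195 ± 2.84 to 40.4 ± 0.522 FPKM (SD, n = 3 each). Starch breakdown genes fell in 19 of 28 members, rose in 6 and did not pass in 3 (camera adjusted p = 0.0382; adjusted p = 0.309 with an estimated correlation), and alpha-amylase 2 (NNU_23926) fell by 3.89 on the log2 scale. Scaled by total counts alone, 14 starch breakdown genes fell and 10 rose. Ranked by fold change, neither starch list passed (adjusted p = 0.276 for synthesis and 0.159 for breakdown); starch synthesis also did not pass without a filter on low counts (adjusted p = 0.11), nor starch breakdown on log2(FPKM + 1) (adjusted p = 0.0607).

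**Figure D2:**
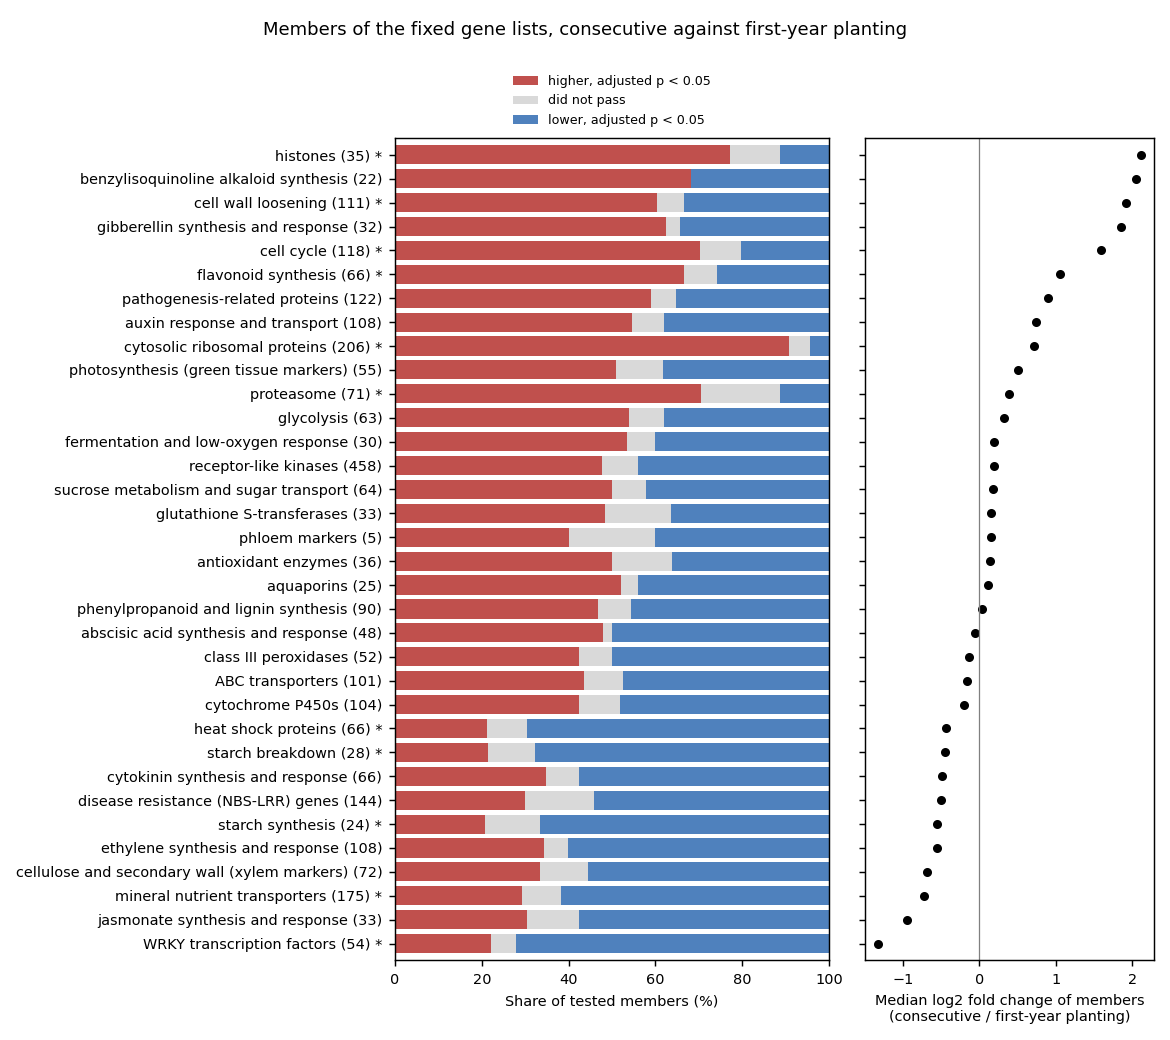
Left, share of tested members of each fixed gene list that were higher, lower or did not pass at adjusted p below 0.05, with the number tested in parentheses and an asterisk on the 11 lists that passed camera; right, median log2 fold change of each list. Histones have the highest median, 2.12, and WRKY transcription factors the lowest, -1.33; scaled by total counts alone the medians of class III peroxidases, abscisic acid genes, ABC transporters and cytochrome P450s turn positive.

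Lists of hormone genes, and of defence genes other than WRKY transcription factors, did not pass camera. Most of their members differed singly, but so did 85.3% of all tested genes. Ranked by fold change, the gibberellin (adjusted p = 0.00379), auxin (adjusted p = 0.00501), jasmonate (adjusted p = 0.0194), pathogenesis-related and NBS-LRR lists (adjusted p = 0.0213 for each) passed in limma, and on log2(FPKM + 1) the ethylene (adjusted p = 0.0137), jasmonate (adjusted p = 0.0163) and NBS-LRR lists (adjusted p = 0.022) passed. With an estimated correlation none of these 6 passed, with adjusted p from 0.309 (NBS-LRR) to 0.683 (ethylene). Jasmonate genes fell in 19 of 33 members and rose in 10 (camera adjusted p = 0.0567), and the jasmonate repressor gene TIFY 10B (NNU_11760) fell from 1204 ± 23.3 to 71.1 ± 1.06 FPKM (SD, n = 3 each). Ethylene genes fell in 65 of 108 members and rose in 37 (adjusted p = 0.0693), and the factor ERF026-like (NNU_08186) fell by 5.15 on the log2 scale. Disease resistance genes of the NBS-LRR class fell in 78 of 144 members and rose in 43 (adjusted p = 0.0703), or 63 and 59 scaled by total counts alone; the TMV resistance protein N-like gene BGI_novel_G000395 fell by 2.03. Cytokinin genes fell in 38 of 66 members and rose in 23 (adjusted p = 0.144), and zeatin O-glucosyltransferase-like (NNU_01664) fell by 4.32. Gibberellin genes rose in 20 of 32 members and fell in 11 (adjusted p = 0.109), and the gibberellin-regulated protein 6-like gene NNU_07268 rose from 2.55 ± 0.43 to 678 ± 25.3 FPKM (SD, n = 3 each). Auxin genes rose in 59 of 108 members and fell in 41 (adjusted p = 0.17), and auxin response factor 8 (NNU_17698) rose by 3.87. Pathogenesis-related proteins rose in 72 of 122 members and fell in 43 (adjusted p = 0.109), and the lipid-transfer protein 1-like gene NNU_12227 rose by 5.47. Abscisic acid genes rose in 23 of 48 members and fell in 24 (adjusted p = 0.826); their median of -0.06 turned to 0.26 scaled by total counts alone, and the abscisic stress-ripening protein 2-like gene NNU_20033 fell by 10.29. Receptor-like kinases rose in 218 of 458 members and fell in 202 (camera adjusted p = 0.73), or 242 and 175 scaled by total counts alone. The inactive receptor-like kinase gene NNU_17668 rose by 7.13.

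Other lists of secondary metabolism and walls, apart from flavonoid synthesis and cell wall loosening, did not pass camera. Ranked by fold change, the benzylisoquinoline alkaloid (adjusted p = 0.00223), cellulose and secondary wall (adjusted p = 0.00416) and class III peroxidase lists (adjusted p = 0.0167) passed in limma, and on log2(FPKM + 1) the cellulose and secondary wall list passed (adjusted p = 0.0137). With an estimated correlation none of these 3 passed (adjusted p = 0.428 for alkaloid, 0.309 for cellulose and secondary wall and 0.724 for peroxidase genes). Benzylisoquinoline alkaloid genes rose in 15 of 22 members and fell in 7 (adjusted p = 0.0774), and the (RS)-norcoclaurine 6-O-methyltransferase-like gene NNU_23168 rose from 1.01 ± 0.118 to 89.9 ± 1.66 FPKM (SD, n = 3 each). Cellulose and secondary wall genes, taken as xylem markers, fell in 40 of 72 members and rose in 24 (adjusted p = 0.0567), and cellulose synthase subunit 7 (NNU_12044), which acts in secondary walls, fell from 46.8 ± 1.04 to 0.347 ± 0.0416 FPKM (SD, n = 3 each). Without first-year replicate 2 both this list and the jasmonate list passed (adjusted p = 0.046 for each). Phenylpropanoid and lignin genes rose in 42 of 90 members and fell in 41 (adjusted p = 0.73), with a median of 0.03 against a downward test direction, and 4-coumarate--CoA ligase 2-like (NNU_14758) fell by 6.48. Class III peroxidases rose in 22 of 52 members and fell in 26 (adjusted p = 0.641), a median of -0.14 that turned to 0.18 scaled by total counts alone, and peroxidase 47-like (NNU_24553) fell by 3.39. Cytochrome P450s rose in 44 of 104 members and fell in 50 (adjusted p = 0.641); their median of -0.20 turned to 0.12 in the same way, and the P450 94C1-like gene NNU_19064, with fractional counts, fell by 5.51. Glutathione S-transferases rose in 16 of 33 members and fell in 12 (adjusted p = 0.701), or 19 and 9 scaled by total counts alone, and the member NNU_15680 fell by 5.08. Antioxidant enzymes rose in 18 of 36 members and fell in 13 (adjusted p = 0.641), or 22 and 9 scaled by total counts alone, and catalase isozyme 1 (NNU_23981) fell by 5.99.

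Apart from the starch and mineral nutrient transporter lists, lists of carbon metabolism, transport and other tissues did not pass camera and were mixed. Sucrose metabolism and sugar transport genes rose in 32 of 64 members and fell in 27 (adjusted p = 0.826), with a median of 0.18 and a mean of -0.06. Sucrose synthase (NNU_19077), which cleaves sucrose in sink organs, rose by 3.25 on the log2 scale. Glycolysis genes rose in 34 of 63 members and fell in 24 (adjusted p = 0.386), or 38 and 16 scaled by total counts alone, and plastidial pyruvate kinase 4 (NNU_02516) fell by 2.79. Genes of fermentation and low-oxygen response rose in 16 of 30 members and fell in 12 (adjusted p = 0.437), or 20 and 4 scaled by total counts alone; alcohol dehydrogenase class-3 (NNU_10239), a formaldehyde-oxidising enzyme, rose by 2.92. Aquaporins rose in 13 of 25 members and fell in 11 (adjusted p = 0.641), and NIP5-1 (NNU_10811), a boric acid channel, fell by 5.18. ABC transporters rose in 44 of 101 members and fell in 48 (adjusted p = 0.826), with a median of -0.16 that turned to 0.15 scaled by total counts alone and a mean of 0.48; the B family member 19 gene NNU_07236 rose by 5.38. Green tissue markers of photosynthesis rose in 28 of 55 members and fell in 21 (adjusted p = 0.641), and Rubisco activase (NNU_08639) rose by 4.37. Of 5 phloem markers 2 rose and 2 fell (adjusted p = 0.809), with a median of 0.15 and a mean of -1.31, and PHLOEM PROTEIN 2-LIKE A3 (NNU_14790) fell by 7.34. Adjusted over the list alone, the counts of rising and falling members were those given for every list except cell cycle (84 rose), ABC transporters (49 fell) and receptor-like kinases (219 rose and 203 fell).

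With the correlation between genes estimated from these libraries, 0 of the 34 lists passed camera, 4 had an unadjusted p below 0.05, and fry, which does not compare a list with other genes, called all 34. Genes of a list are not independent of each other. Among the called lists the estimate was 0.0015 for cell cycle, 0.0039 for starch breakdown and 0.0046 for mineral nutrient transporters, below the preset 0.01. For these lists a larger correlation is not why the call was lost. In the other called lists the estimate lay between 0.0405 and 0.156. For cell cycle genes the unadjusted camera p went from 5.71e-06 to 0.00356 despite the lower estimate. The settings thus differ in more than the size of the correlation, and what made the other lists fail was not separated.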

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

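The glmTreat test, the ranking of lists by fold change and the lists without mismatched members were chosen after seeing the data. All 62 named genes kept their direction and their side of the threshold under each of the 14 alternatives run on genes. They had been chosen for large folds or small p in the same libraries, so this was favoured in advance. Of the 17592 genes called in the main fit, the alternatives also called between 15767 (limma on log2(FPKM + 0.1)) and 17539 (RLE size factors). Gene counts stayed within 1.5 times under each of these, except that limma on log2(FPKM + 1) called 2582 genes at least 2-fold lower against 4230. With 0.1 added it called 3171, near the 3233 under total counts alone, which like FPKM carry no TMM factor. The shares of scaling and of the added constant were not tested. Against a 2-fold change glmTreat called 4372 genes higher and 3745 lower. Leaving out each library gave 8809 to 8895 genes higher, 8343 to 8453 lower, 4985 to 5026 at least 2-fold higher and 4224 to 4264 at least 2-fold lower, with 6 lists higher each time and 5 to 7 lower. Gene lists depended on the test: 0 higher and 0 lower passed with an estimated correlation, 18 and 16 by fry, 5 and 8 on log2(FPKM + 1), and 9 and 7 ranked by fold change. The fold ranking lost the proteasome and both starch lists and added benzylisoquinoline alkaloid, gibberellin, cellulose and secondary wall, auxin, class III peroxidase, jasmonate, pathogenesis-related and NBS-LRR lists. The directions of some lists that did not pass reversed, with the cause not tested. Sucrose metabolism turned downward under fry and fold ranking (median 0.187 in both) and on log2(FPKM + 1) (0.427), and ABC transporters turned upward under fry and fold ranking (-0.103 in both). Photosynthesis turned downward without a filter (-0.119), receptor-like kinases on log2(FPKM + 1) (0.292) and antioxidant enzymes under fold ranking (0.144). Without mismatched members all 34 lists kept their call. Replicate numbers did not pair the samples (correlations of deviations 0.0289, 0.0242 and 0.0118), and samples share only a number: the replicate block gave 8948 genes higher and 8512 lower, 5016 and 4236 at least 2-fold, and 6 and 5 lists. Depth limits genes near 3 counts over a group.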

Other observations

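The 4 lists of this part (cuticle and wax, suberin and Casparian strip, root identity, shoot and leaf identity) were written after the genes with the largest changes had been seen. Adjusted p-values of these lists, by camera and by fold ranking, were adjusted over the 4 lists only. Also set after that point were the ranking of lists by fold change and the test of replicate spread. So were the counts by direction under other scalings and the test of 1 offset for all genes. The genes named here were chosen after their values were seen. Cuticle and wax genes, which build the surface layer of aerial organs, rose in 24 of 31 members and fell in 5, and this was the 1 list of the 4 that passed camera (adjusted p = 0.000875; adjusted p = 0.0542 with an estimated correlation). ECERIFERUM 1-like (NNU_18192), of wax alkane synthesis, rose from 0.743 ± 0.166 to 120 ± 1.38 FPKM (SD, n = 3 each), and ECERIFERUM 3 (NNU_20797) rose from 0.13 ± 0.0361 to 29.6 ± 1.07 FPKM. Suberin and Casparian strip genes, which seal root cell walls, did not pass (18 of 42 rose and 22 fell, camera adjusted p = 0.312; adjusted p = 0.303 with an estimated correlation); ranked by fold change they lay lower (adjusted p = 0.0262), a test that partly restates the falls from which the list was written. Glycerol-3-phosphate acyltransferase 5-like (NNU_18740) was at least 272-fold lower in consecutive planting, while the fatty acyl-CoA reductase NNU_25346 rose from 0.21 ± 0.03 to 42.4 ± 1.14 FPKM.

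The stomatal lineage gene SPEECHLESS-like (NNU_01457) had no count in first-year planting and was at least 109-fold higher in consecutive planting, at 4.04 ± 0.547 FPKM. TOO MANY MOUTHS-like (NNU_26674) had a ratio of 904 with a 95% counting interval from 162 to 35740. EPIDERMAL PATTERNING FACTOR-like protein 2 (NNU_09669) fell by 3.29 on the log2 scale. Proteins 4 (NNU_06318) and 5 (NNU_12248) of that family rose by 5.92 and 0.30. Their shoot and leaf identity list rose in 22 of 34 members and fell in 10. Metallothionein-like protein 3 (NNU_26001), a metal-binding protein, fell from 14120 ± 187 to 93.3 ± 3.33 FPKM (SD, n = 3 each). Among 100 gene ontology processes with 20 to 500 tested genes, 5 lay higher and 2 lower by camera. Microtubule-based movement rose in 20 of 21 genes and fell in 1 (adjusted p = 6e-05; adjusted p = 0.559 with an estimated correlation). With an estimated correlation 0 processes passed, and 7 had an unadjusted p below 0.05. Of 1993 tested loci with a separate identifier prefix, 713 were higher and 815 lower, against 8302 and 7762 of 18636 reference genes.

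The first pattern followed up was named, from the top genes, as lower suberin genes and higher cell cycle genes in consecutive planting, and its suberin part passed as a list when ranked by fold change (adjusted p = 0.0262) but not by limma camera (adjusted p = 0.312). Transcript length bias was argued against by Spearman's rho of -0.047 between fold change and length across genes, which are not independent. A candidate explanation is that the first-year libraries held more root tissue, but root identity genes, with a median log2 change of -1.218 (3 of 11 rose and 8 fell), did not pass limma camera (unadjusted p = 0.138), with members from the phosphate transporter 1-4-like gene NNU_03436, which fell by 5.95, to the SHORT-ROOT-like gene NNU_02726, which rose by 7.28. Another is that the consecutive-planting libraries held more growing tip or bud tissue: histones lay at a median of 2.11, which is close to the cell cycle pattern itself and not independent of it, while shoot and leaf identity genes (22 of 34 rose and 10 fell, median 0.701) did not pass limma camera (unadjusted p = 0.176), and the cuticle and wax list, which was not part of that test and was picked out after its result was seen, points the same way (24 of 31 rose, camera adjusted p = 0.000875), although it did not pass with an estimated correlation (adjusted p = 0.0542). Both cannot be told apart from an effect of planting history, because each group comes from its own pools and the labels give no part or stage of the rhizome.

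The second pattern was the share of genes called. A single wrong factor between the groups as the whole cause was argued against, since the number of genes at least 2-fold plus 2 SE away, 7901 without an offset, kept at least 99.99% of its size under each offset tried for all log2 fold changes. How far scaling sets the count in each direction stays open, since the genes at least 2-fold higher or lower moved by up to 1.308 times under RLE or total count scaling; their sum moved by at most 1.027 times, which decides nothing because gains on 1 side offset losses on the other. The small spread between libraries, a biological coefficient of variation of 3.633%, may let small differences pass, and 46.1% of called genes passed a test against a 2-fold change. Whether the 3 libraries of a group share RNA, a plant or a pool stays open.

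The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 17592 genes, 9243 of them at least 2-fold, and 1 of the 10 splits, the real one, gave as many. The other splits gave at most 0 by edgeR, with 9 to 21 genes at an unadjusted p below 0.05. Each of them mixes the groups on either side, so the group difference widens the spread within a side. Few calls could then arise, and the contrast with the real split decides nothing. For gene lists the real split gave 11 and the other splits 6 to 10, so that 1 of 10 was as large. The other splits keep part of the group difference, so their lists are not a count of false calls.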
